A study of Mus musculus with 27 samples.

How the data were processed

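The series holds 27 mouse samples, each hybridised as biotin-labelled cRNA of total RNA to an Illumina mouse BeadChip, in 5 groups: E13 embryo, E16 embryo, Tbr2 cKO at E13, Tbr2 cKO at E16, and sorted P2 neurons. Groups were taken from the sample titles, since the age given for the E16 embryo samples repeats E13. The protocol text that describes a sort for GFP is repeated for all samples, although only the titles and sources of the P2 samples name it. The embryo arrays, the arrays labelled cKO and the P2 arrays came in 3 separate tables. Within each group arrays are numbered by the order of their columns in the deposited table, which is a name only.

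Per the file headers, the intensity values were deposited as non-normalised average signals per probe. They ran from -50.8 to 48266, so a background had been subtracted before deposit. The detection p-value deposited beside each signal compares the probe with the negative control beads of its array, in 936 steps. The log2 values deposited as the series matrix covered 12377 probes, each with a detection p under 0.05 in all 27 arrays, although 14964 probes met that limit. Their columns shared 1 median, 8.95, as after quantile normalisation. Each of the 27 matrix columns had its best rank match among the signal columns of its own group (lowest best correlation 0.998, highest with another 0.993). The scanner software and the tool behind the matrix are not given in the sources used here.

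The signals of 45281 probes on all 27 arrays were read with R 4.3.3 and processed with limma 3.58.1. Background was corrected by normexp with the negative control distribution inferred from the detection p-values, an offset of 16 was added, and all arrays were quantile normalised together and put on the log2 scale. No deposited signal column was left out. Probes were kept with a detection p under 0.01 in at least 5 arrays, 20498 in all. By the platform annotation 34885 probes had 1 gene symbol, 18 had several and 10378 had none, and 34807 of the symbols matched RefSeq with 0 changed. Of the kept probes 17259 had 1 symbol, and the probe with the highest mean stood for each of 10663 genes, 4352 of which had several kept probes. Among 144 pairs of a named gene and a comparison with several probes, 3 had probes of opposite sign (Dcc and Robo2 between E16 and E13 embryo, Eomes in the interaction), and 0 of these had an unadjusted p under 0.05 in both by limma. Median raw signals ran from 8.51 to 42.3 per array, and 36.9% to 42.9% of probes were detected.

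One linear model with 1 mean per group was fitted over all arrays and moderated by empirical Bayes. It gave 7 comparisons: E16 against E13 in the embryo and in the cKO arrays, cKO against embryo at each stage, the interaction of stage and genotype, and P2 against E16 and against E13 embryo. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. A fold change against a group in which no array held the probe above background was given as a lower bound, computed with that group at the level of its background limit and written as at least that fold. Where only some arrays of a group held it, their number is given. Of 24 gene lists, each measured list with at least 3 genes was tested with camera at a preset correlation of 0.01 and, as an alternative, with a correlation estimated from the data, adjusted over the lists of the comparison. Members were also adjusted over their list alone. The test fry was run as well and is not used here. Erythroid and liver lists had 2 measured genes each and no list test, and of 21 Hox genes 0 were measured.

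The comparisons, the 24 lists, the alternatives and the genes to name were fixed before the data were examined. A thalamus and habenula list and an olfactory bulb list were added after the genes higher in the arrays labelled cKO had been seen. Named genes were Eomes, the 5 largest rises and 5 largest falls among the genes that passed in a comparison, leaving out predicted genes, and up to 4 passing members of each list with the largest change. The genes named as shared by both stages, and those named without array 2 of the E13 cKO group and array 3 of the E16 cKO group, were chosen after their values were seen. On simulated data of 10663 genes with the group sizes of cKO and embryo at E13, 24 of 50 genes changed by 0.5 on the log2 scale were found, 46 of 50 changed by 1, and 50 of 50 changed by 2 or by 4, with 12 false among 195 calls. The other 13 calls were among 15 more genes that had been changed by 1 together, as a list. The simulated noise was independent between genes, and no simulated array lay at the levels of another group. The precision of the real comparisons between genotypes can therefore be lower.

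The alternatives were: no normexp step, scaling each array to a common median, the values of the series matrix, each table normalised separately, no filter on dim probes, detection in every array of a group, the mean of all probes of a gene, an intensity trend with robust moderation, only the compared groups in the fit, and each array left out in turn. A replicate block with the series matrix values, and a fit without the 2 arrays named above, were added after the data were seen. Of 5 pairs of samples with the same number, 0 to 3 correlated above 0.1 in each comparison of groups. The highest mean, between genotypes at E16, was 0.254, against -0.0512 for other pairs, and 3 of 5 matched best with their own number. Between genotypes at E13 the means were 0.102 and -0.0181, with 2 of 5. A pairing between genotypes is thus possible, but the labels name no pairs, and the comparisons were made unpaired. Groups were compared without covariates, as the labels give no sex, litter or slide. The names of the signal columns hold numbers. At E13 the number of every cKO column adjoins that of an embryo column, and at E16 that of most cKO columns does. What these numbers mean is not given, and a pairing by them was not tested.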

Results

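Gene expression in mouse samples was measured on 27 Illumina BeadChip arrays, 1 array per sample. Per the labels, 5 arrays held Tbr2-lineage neurons that were sorted by green fluorescent protein (GFP) from the cortex at postnatal day 2 (P2). The labels put 6 arrays in a group called E13 embryo, 5 in E16 embryo, 5 in Tbr2 conditional knockout (cKO) cortex at E13 and 6 in Tbr2 cKO cortex at E16, where E stands for embryonic day. Tbr2 is the protein of the gene Eomes (Entrez Gene 13813, chromosome 9), a transcription factor of the intermediate progenitors that produce excitatory cortical neurons. The signal columns of the embryo arrays carry the letters WT, which was read as wild type, and their labels name neither a tissue nor a sort of their own. Of the 45281 probes of each array, 39.2% ± 0.638 (SD, n = 6) were detected in E13 embryo, 38.7% ± 0.652 (SD, n = 5) in E16 embryo, 38.9% ± 0.583 (SD, n = 5) in E13 cKO, 38.2% ± 1.18 (SD, n = 6) in E16 cKO and 41.5% ± 1.56 (SD, n = 5) in the P2 neurons. The number of arrays per group limited the precision. Normalised log2 signals of 10663 genes were compared with limma, and each value below is a group mean ± SD or a log2 change ± SE from that fit.

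The P2 neurons lay far from all embryonic arrays along the first principal component, which held 63.6% of the variance over all 27 arrays. Among the 22 embryonic arrays the first component, 41.3% of the variance, ran from E13 to E16, and the second, 10.6%, placed most arrays labelled cKO below the embryo arrays. On that second component array 2 of the E13 cKO group lay at 10.7, inside the 5.26 to 15.8 of the E13 embryo arrays, while the other 4 arrays labelled cKO at E13 lay between -26.2 and -2.70. Array 3 of the E16 cKO group lay at 5.89, inside the -4.18 to 12.1 of the E16 embryo arrays, while the other 5 lay between -19.7 and -2.80, of which array 2, at -2.80, was also inside the range of the embryo arrays. Counts that compare genotypes are therefore given with and without these 2 arrays, a choice made after the data were seen. Since the 2 arrays were left out for their likeness to embryo, counts without them are larger by that choice. Changes and p-values between genotypes from that fit are favoured by it too and are no independent test.

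**Figure D1:**
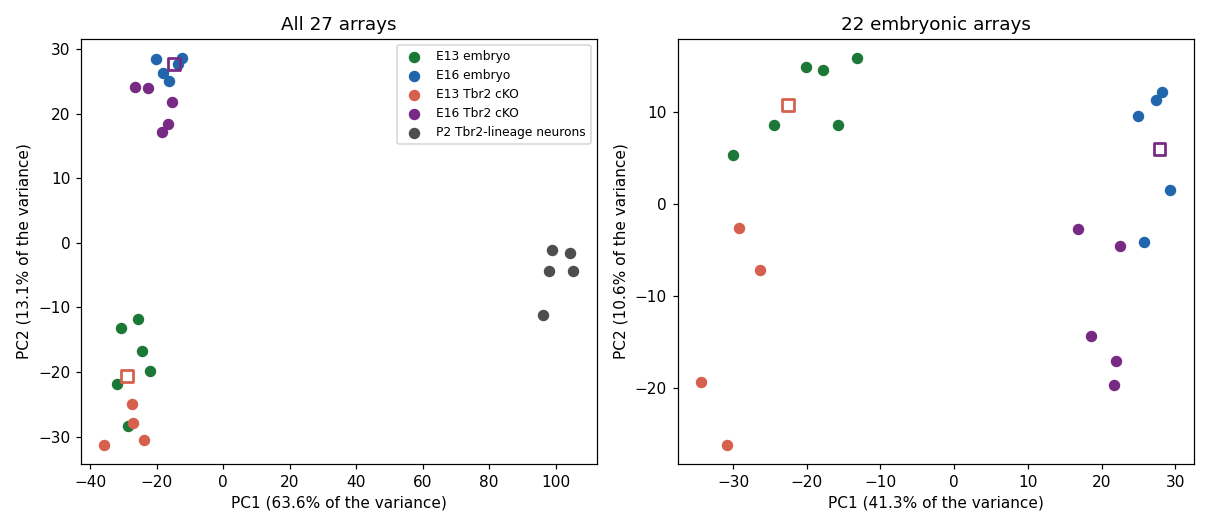
Principal components of the normalised log2 signals of 10663 genes, over all 27 arrays (left) and over the 22 embryonic arrays (right), with 1 point per array coloured by group and the share of variance on each axis. Open squares mark array 2 of the E13 cKO group and array 3 of the E16 cKO group, which lie among the embryo arrays of their stage.

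The change between E13 and E16 was read from the embryo arrays. Sla, an adaptor protein gene, rose 14.9-fold (log2 change 3.89 ± 0.39 SE; limma adjusted p = 4.2e-08), from 6.30 ± 1.15 (SD, n = 6) to 10.20 ± 0.52 (SD, n = 5), and was higher in 5 of 5 E16 arrays than in any E13 array. The transcription factor gene Fezf1, from 11.81 ± 0.56 (SD, n = 6) to 5.96 ± 1.68 (SD, n = 5), fell 57.6-fold. The imprinted gene Dlk1 fell 26.1-fold and the homeobox gene Uncx 24.8-fold, all 3 in 5 of 5 arrays. Of these, Sla was above background in 4 of 6 E13 arrays, and Fezf1 and Uncx in 2 and 3 of 5 E16 arrays. Eomes itself fell by 0.75 ± 0.20 on the log2 scale (adjusted p = 0.0062), from 11.25 ± 0.27 (SD, n = 6) to 10.51 ± 0.32 (SD, n = 5), and 4 of 5 E16 arrays lay below every E13 array. Of 10663 genes, 1223 rose and 1318 fell, with at least a 2-fold change for 212 and 329 of them. With each array scaled to a common median, 651 rose and 1006 fell.

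Cell type groups of the embryo arrays moved in distinct directions between E13 and E16. Intermediate progenitor genes fell in 11 of 15 measured members, with 0 risen and 4 not passing (1 risen and 11 fallen when adjusted over the list alone), led by the Notch ligand genes Dll3, 3.00-fold, and Dll1, 2.29-fold, and the proneural gene Neurog1, 2.15-fold. Their camera adjusted p was 3.6e-05, and the adjusted p was 0.088 with an estimated correlation. Upper-layer neuron genes rose in 8 of 11 and 1 fell (10 and 1 when adjusted over the list alone; camera adjusted p = 5.5e-07, and adjusted p = 0.0039 with an estimated correlation). Among them Inhba rose 6.18-fold, Mef2c 3.24-fold and Cux2 2.97-fold, while Plxnd1 fell 2.67-fold. Genes of Cajal-Retzius cells, early neurons of the cortical surface, fell in 6 of 7 (6 when adjusted over the list alone; camera adjusted p = 8.3e-07, and adjusted p = 0.024 with an estimated correlation), with Ebf2 12.3-fold, Lhx1 9.22-fold and Lhx5 8.13-fold lower. Cell cycle genes fell in 14 of 18, none rose and 4 did not pass (15 fallen when adjusted over the list alone; camera adjusted p = 3.6e-08, and adjusted p = 0.21 with an estimated correlation), including Cdc20, 2.57-fold, Birc5, 2.54-fold, and Cdk1, 2.50-fold. Of the genes named here, Inhba was above background in 1 of 6 E13 arrays, and Neurog1, Ebf2 and Lhx5 in 1, 2 and 1 of 5 E16 arrays.

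Some genes of neuronal excitability rose between E13 and E16. Glutamate receptor and ion channel genes rose in 6 of 17 and 1 fell (8 and 1 when adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation), with Grin2b 2.66-fold and Gria2 2.61-fold higher and Grik2 1.68-fold lower. Immediate early genes rose in 2 of 7 (4 when adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.40 with an estimated correlation), Fos 2.84-fold and Jun 1.33-fold. Their list was set up for immediate early genes and dissociation stress together, so it does not mark excitability alone. Skeletal muscle genes, which mark tissue from outside the brain, fell in 2 of 4, with 3 when adjusted over the list alone. Tnnt1 fell 2.07-fold and Mylpf 2.05-fold, each above background in 1 of 5 E16 arrays (camera adjusted p = 0.019, and adjusted p = 0.085 with an estimated correlation).

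Other groups moved both ways and passed no list test between E13 and E16. Of 16 radial glia genes 3 rose and 2 fell (camera adjusted p = 0.92), with the glutamate transporter gene Slc1a3 4.48-fold higher and the intermediate filament gene Vim 2.91-fold lower. Newborn and migrating neuron genes split 3 to 3 of 15, with Nrp1 3.28-fold higher and Rnd2 1.91-fold lower. Deep-layer neuron genes split 3 to 6 of 15, with Crym 5.41-fold higher (above background in 4 of 6 E13 arrays) and Rprm 2.01-fold lower. Synaptic protein genes split 5 to 4 of 18, with Camk2b 2.13-fold higher and Sv2b 6.12-fold lower. Axon guidance genes split 3 to 6 of 20, with Robo2 2.35-fold higher and Dcc 3.07-fold lower, 2 genes for which a second probe gave the opposite sign, though not with an unadjusted p under 0.05 for both probes. Chromatin regulators split 2 to 2 of 19, delta protocadherins 3 to 2 of 9, astrocyte genes 1 to 2 of 7, and choroid plexus and cortical hem genes 0 to 2 of 5, with Otx2 2.79-fold lower. None of the 9 ventral progenitor and interneuron genes, 4 oligodendrocyte lineage genes, 10 endothelial and pericyte genes, 11 microglia genes and 5 meninges genes passed in limma, and most endothelial and microglia members were not above background on any array of either group. Of the erythroid list 2 genes were measured and 1 rose, of the liver list 2 were measured and 1 fell, and of 21 Hox genes 0 passed the filter.

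The stages were also compared in the arrays labelled cKO. Sla rose 24.8-fold (log2 change 4.63 ± 0.39 SE; limma adjusted p = 2.5e-09) from 5.69 ± 0.68 (SD, n = 5) to 10.32 ± 0.46 (SD, n = 6), and the transcriptional repressor gene Bcl6 rose 9.98-fold, each in 6 of 6 arrays. Fezf1 fell 90.5-fold, Dlk1 31.9-fold, and Crabp2, a retinoic acid binding protein gene, 15.1-fold, each in 6 of 6 arrays. Sla was above background in 2 of 5 E13 arrays, and Fezf1 and Crabp2 in 1 and 4 of 6 E16 arrays, so their folds depend on the background level. Eomes changed by -0.43 ± 0.20 (SE; adjusted p = 0.11), from 11.52 ± 0.10 (SD, n = 5) to 11.09 ± 0.46 (SD, n = 6), which did not pass. Its second probe gave -0.760 (95% limits -1.21 to -0.312), against -0.751 (-1.20 to -0.303) in the embryo arrays. Of 10663 genes 1241 rose and 1533 fell, 44.7% of the calls higher. With each array scaled to a common median, 582 rose and 1323 fell, 30.6% higher. Without the 2 arrays that lay among the embryo arrays, 1031 rose and 1365 fell.

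The lists were tested between stages in the arrays labelled cKO as well. Intermediate progenitor genes fell in 8 of 15 and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.22 with an estimated correlation). Dll3 (above background in 5 of 6 E16 arrays) was 2.49-fold lower and Dll1 2.24-fold, while the somatostatin receptor gene Sstr2 rose 2.10-fold. Upper-layer genes rose in 8 of 11 and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 1.7e-05, and adjusted p = 0.014 with an estimated correlation), with Inhba 5.67-fold (above background in 2 of 5 E13 arrays) and Cux2 2.80-fold higher. Cajal-Retzius genes fell in 5 of 7 (5 when adjusted over the list alone; camera adjusted p = 2.6e-04, and adjusted p = 0.12 with an estimated correlation), and the gene for the secreted protein reelin, Reln, was 4.93-fold lower. Cell cycle genes fell in 13 of 18 (15 when adjusted over the list alone; camera adjusted p = 9.2e-08, and adjusted p = 0.22 with an estimated correlation), with Top2a 2.93-fold lower. Glutamate receptor and channel genes rose in 8 of 17 (8 risen and 1 fallen when adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.14 with an estimated correlation), with Gria2 3.38-fold higher. Choroid plexus and hem genes fell in 4 of 5 (4 when adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.23 with an estimated correlation). Otx2 (above background in 4 of 6 E16 arrays) was 3.96-fold lower and Ttr at least 2.73-fold lower, with Ttr at 7.26 ± 3.12 (SD, n = 5) at E13. Array 4 held Ttr at 12.5 there and the others at 4.78 to 7.34, and without it Ttr was at least 1.10-fold lower and did not pass (adjusted p = 0.098). Skeletal muscle genes fell in 2 of 4 (2 when adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.12 with an estimated correlation). The immediate early list, which passed in embryo, did not pass here, with 1 of 7 risen (camera adjusted p = 0.19).

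Stage changes were shared by both sets of arrays. Of the genes that rose with stage, 865 rose in both, against 142 expected by chance, and 1017 fell in both, against 189, while 1 gene was called in opposite directions. Across all genes, which are not independent replicates, the log2 changes had a Pearson r of 0.880 and a Spearman rho of 0.819.

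**Figure D2:**
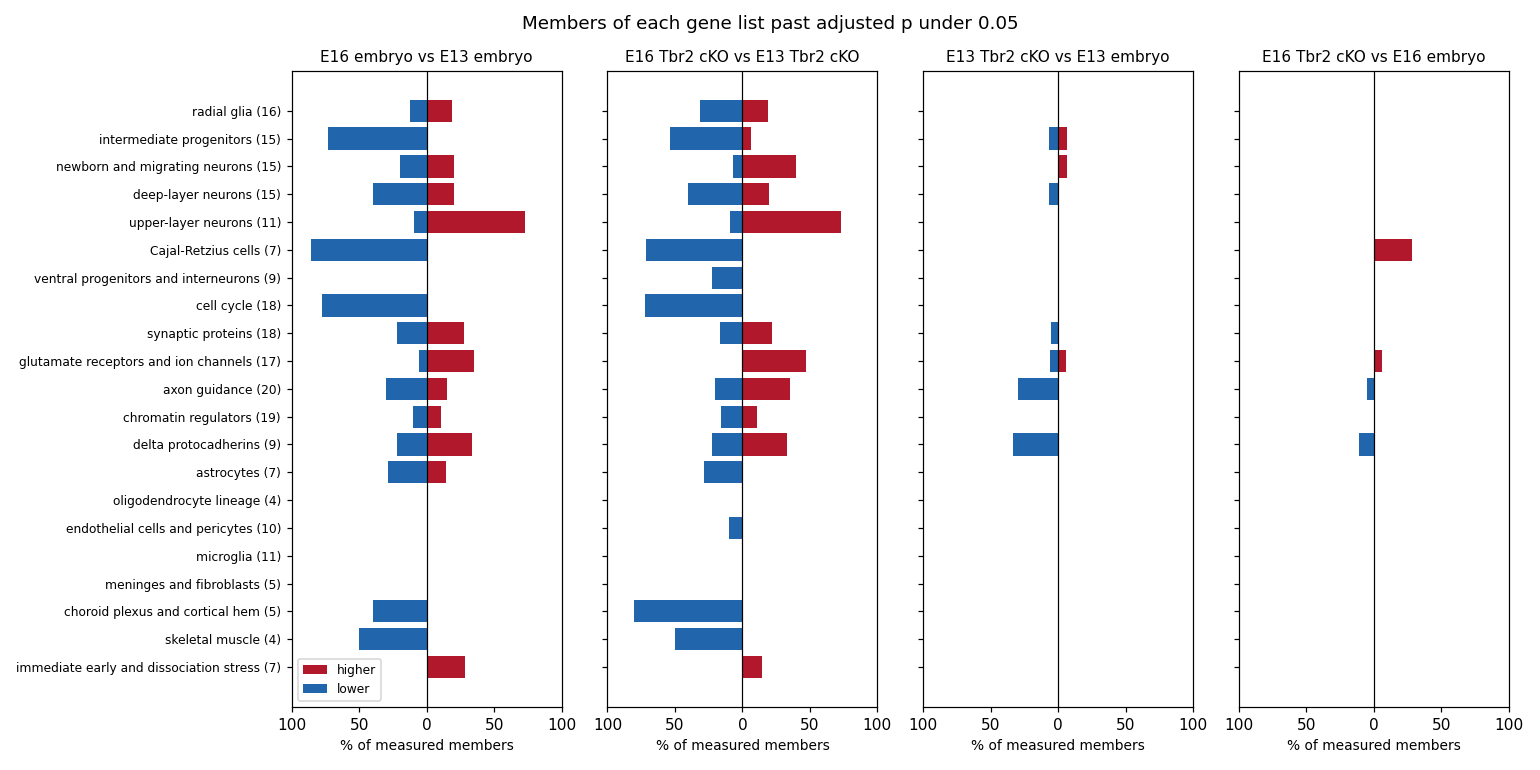
Percentage of the measured members of each gene list (number in parentheses) that were higher (red, to the right) or lower (blue, to the left) at a limma adjusted p under 0.05, in 4 comparisons. Both stage comparisons show upper-layer genes mostly higher and intermediate progenitor, Cajal-Retzius and cell cycle genes mostly lower, while few members pass between genotypes.

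At E13, the arrays labelled cKO were compared with the embryo arrays. Eomes was not lower: it was 11.52 ± 0.10 (SD, n = 5) in the arrays labelled cKO and 11.25 ± 0.27 (SD, n = 6) in embryo, a log2 change of 0.27 ± 0.20 SE (limma adjusted p = 0.78). A second Eomes probe gave 0.45, with 95% limits of 0.00032 to 0.895. Which part of the gene was deleted is not known here, and a probe outside that part would check nothing. Pdzrn3, a ubiquitin ligase gene, was 8.70-fold higher (log2 change 3.12 ± 0.50 SE; adjusted p = 0.0018), and the homeobox gene Gbx2 was 5.63-fold higher (2.49 ± 0.61 SE; adjusted p = 0.032). Rgs4, 5.18-fold, the transporter gene Slco4a1, at least 2.82-fold, and Lmcd1, 4.71-fold, rose too, each of the 5 in 4 of 5 arrays. The sorting receptor gene Sorl1 fell 4.14-fold (adjusted p = 0.0046), the chemokine gene Cxcl12 3.94-fold and the cadherin gene Cdh8 3.21-fold, each in 4 of 5 arrays, and Fst 3.19-fold. Cdh8 and Fst were above background in 3 and 4 of 5 arrays labelled cKO.

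The lists of axon guidance genes and delta protocadherins shifted down at E13, with a part of their members passing. Of 20 axon guidance genes 6 fell, 0 rose and 14 did not pass (7 fallen when adjusted over the list alone; camera adjusted p = 7.6e-06, and adjusted p = 0.037 with an estimated correlation). The receptor gene Robo2 was 2.34-fold lower (8.28 ± 0.71 against 9.51 ± 0.05; SD, n = 5 and 6), Unc5c 2.19-fold, Slit3 1.97-fold (above background in 3 of 5 arrays labelled cKO) and Epha7 1.95-fold. Of 9 delta protocadherin genes, which encode adhesion proteins, 3 fell and 6 did not pass (4 fallen when adjusted over the list alone; camera adjusted p = 1.1e-04, and adjusted p = 0.027 with an estimated correlation): Pcdh20 1.98-fold, Pcdh19 1.74-fold and Pcdh17 1.52-fold. Single members of other lists moved as well: the deep-layer transcription factor gene Tbr1 fell 2.23-fold (adjusted p = 0.017), the vesicular glutamate transporter gene Slc17a7 2.83-fold, the glutamate receptor gene Gria3 1.97-fold and Sstr2 2.59-fold, while Insm1 rose by 0.68 on the log2 scale, Nrp1 1.51-fold and the potassium channel gene Kcnd2 1.45-fold. The intermediate progenitor list split 1 to 1 of 15 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.060).

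Several lists shifted upwards at E13 without any member passing on its own. The camera adjusted p was 8.8e-05 for cell cycle, 0.0020 for endothelial cells and pericytes, 0.0058 for ventral progenitors and interneurons, 0.0089 for choroid plexus and hem, and 0.016 for each of radial glia and microglia. With an estimated correlation the adjusted p was 0.45, 0.43, 0.49, 0.43, 0.58 and 0.45 in that order. In limma 0 members of these 6 lists passed, also when adjusted over each list alone, among 1052 of 10663 genes at an unadjusted p under 0.05. Without array 4 of the E13 cKO group, in which the choroid plexus gene Ttr reached 12.5, all of them but the cell cycle list no longer passed. The list medians moved from 0.27 to 0.096 for radial glia, 0.78 to 0.17 for ventral progenitors and interneurons, 0.30 to 0.039 for endothelial cells, 0.16 to 0.021 for microglia and 0.60 to 0.34 for choroid plexus. The synaptic list shifted down, with 1 of 18 members lower (1 when adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.43 with an estimated correlation), and lost its call without any 1 of 6 arrays.

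Of 10663 genes, 79 were higher and 76 lower in the arrays labelled cKO at E13, with at least a 2-fold change for 35 and 34. Without the 2 arrays that lay among the embryo arrays, 209 were higher and 185 lower, and these included all 79 and 76. Without array 1, 3, 4 or 5 of the E13 cKO group the counts were 12 and 15, 30 and 29, 24 and 20, and 30 and 29. With only the compared groups in the fit, 7 were higher and 4 lower, and 24 of 25 named genes lost their call. The calls at E13 thus depend on the spread estimated over all groups. The labels name cortex for the cKO arrays and no tissue for the embryo arrays, and each genotype was deposited in a table of its own.

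At E16 the arrays labelled cKO were compared with the embryo arrays in the same way. Eomes was 11.09 ± 0.46 (SD, n = 6) against 10.51 ± 0.32 (SD, n = 5), a log2 change of 0.59 ± 0.20 SE (limma adjusted p = 0.27), and its second probe gave 0.44 (95% limits -0.0086 to 0.886). Without the 2 arrays that lay among the embryo arrays its change was 0.75 ± 0.18 SE. In that fit Eomes passed as 1.68-fold higher in the arrays labelled cKO (limma adjusted p = 0.017), but the choice of arrays favours such a call. Gbx2 was at least 7.51-fold higher (log2 change 3.71 ± 0.61 SE; adjusted p = 0.0041), at 8.67 ± 1.82 (SD, n = 6) while no E16 embryo array was above background. The transcription factor gene Ebf3, 6.68-fold (adjusted p = 0.0079), Lmcd1, 6.21-fold, the cadherin-related gene Cdhr1, at least 2.47-fold, and Uncx, 3.81-fold, rose, and each of the 5 was above every embryo array in 5 of 6 arrays. The neuropeptide gene Tac2 fell at least 1.41-fold (log2 change -1.52 ± 0.18 SE; adjusted p = 7.6e-05) in 6 of 6 arrays, the potassium channel gene Kcnh3 2.69-fold, Col22a1 2.65-fold, the calcium sensor gene Hpca 2.64-fold and Trim9 2.44-fold. Uncx was above background in 3 of 5 embryo arrays, and Kcnh3 and Col22a1 in 1 and 2 of 6 arrays labelled cKO, so these folds depend on the background level. A second Tac2 probe, which the filter removes, changed by -0.54 with no filter and did not pass (limma adjusted p = 0.38).

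Few list members passed at E16. Of 7 Cajal-Retzius genes 2 rose (2 risen and 1 fallen when adjusted over the list alone; camera adjusted p = 0.081): Ebf3 and its relative Ebf2, 3.21-fold (above background in 2 of 5 embryo arrays). Slit3 was 2.02-fold lower, 1 of 20 axon guidance genes (3 fallen when adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.37 with an estimated correlation). Pcdh20 was 2.32-fold lower, 1 of 9 delta protocadherins (1 risen and 3 fallen when adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.20 with an estimated correlation). Gria1, a glutamate receptor gene, was 2.20-fold higher, 1 of 17 in its list (2 when adjusted over the list alone; camera adjusted p = 0.37). Intermediate progenitor and cell cycle genes shifted upwards with 0 of 15 and 0 of 18 members passing in limma, 5 and 0 when adjusted over the list alone, among 749 of 10663 genes at an unadjusted p under 0.05. The camera adjusted p was 1.6e-04 for both, and the adjusted p was 0.20 and 0.38 with an estimated correlation. With the 2 arrays that lay among the embryo arrays left out, 2 of these lists passed camera with an estimated correlation too. They were intermediate progenitors (adjusted p = 0.027) and delta protocadherins (0.045), while cell cycle (0.54) and axon guidance (0.32) did not. As the 2 arrays were left out for their likeness to embryo, these p-values are no independent test.

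Of 10663 genes, 28 were higher and 24 lower in the arrays labelled cKO at E16, with at least a 2-fold change for 20 and 14. Without the 2 arrays that lay among the embryo arrays, 131 were higher and 133 lower, and these included all 28 and 24. Leaving out array 3 of the E16 cKO group gave 115 and 120, and leaving out array 2 of the E16 embryo group gave 8 and 7. With only the compared groups in the fit, 1 was higher and 9 lower, and 10 of 15 named genes lost their call. Most calls at E16 thus depend on the spread estimated over all groups. With the values of the series matrix, which hold 7520 genes, 7 were higher and 14 lower, and with a replicate block added to these, 0 were higher and 9 lower in limma.

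The genotype changes of both stages overlapped in named genes. Gbx2 and Lmcd1, the neuropeptide gene Adcyap1, the transcription cofactor gene Lmo2, Col9a2, Gcg, Gm11346 and Lurap1l were higher at both stages, 8 genes against 0.207 expected by chance (Fisher's exact test, 1-sided, p = 1.7e-11). Kcnh3, Pcdh20, Slit3, Lrrn3, Lypd6 and Tenm4 were lower at both, 6 against 0.171 (Fisher's exact test, 1-sided, p = 1.3e-08). Both p-values count genes as independent, so they do not measure replication over animals. The comparisons of both stages also share the difference between the deposited tables of embryo and cKO arrays. Without the 2 arrays that lay among the embryo arrays, 71 genes were higher at both stages against 2.57 expected and 53 lower against 2.31. Across all genes, which are not independent replicates, the genotype changes at E13 and E16 had a Pearson r of 0.489 and a Spearman rho of 0.343.

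**Figure D3:**
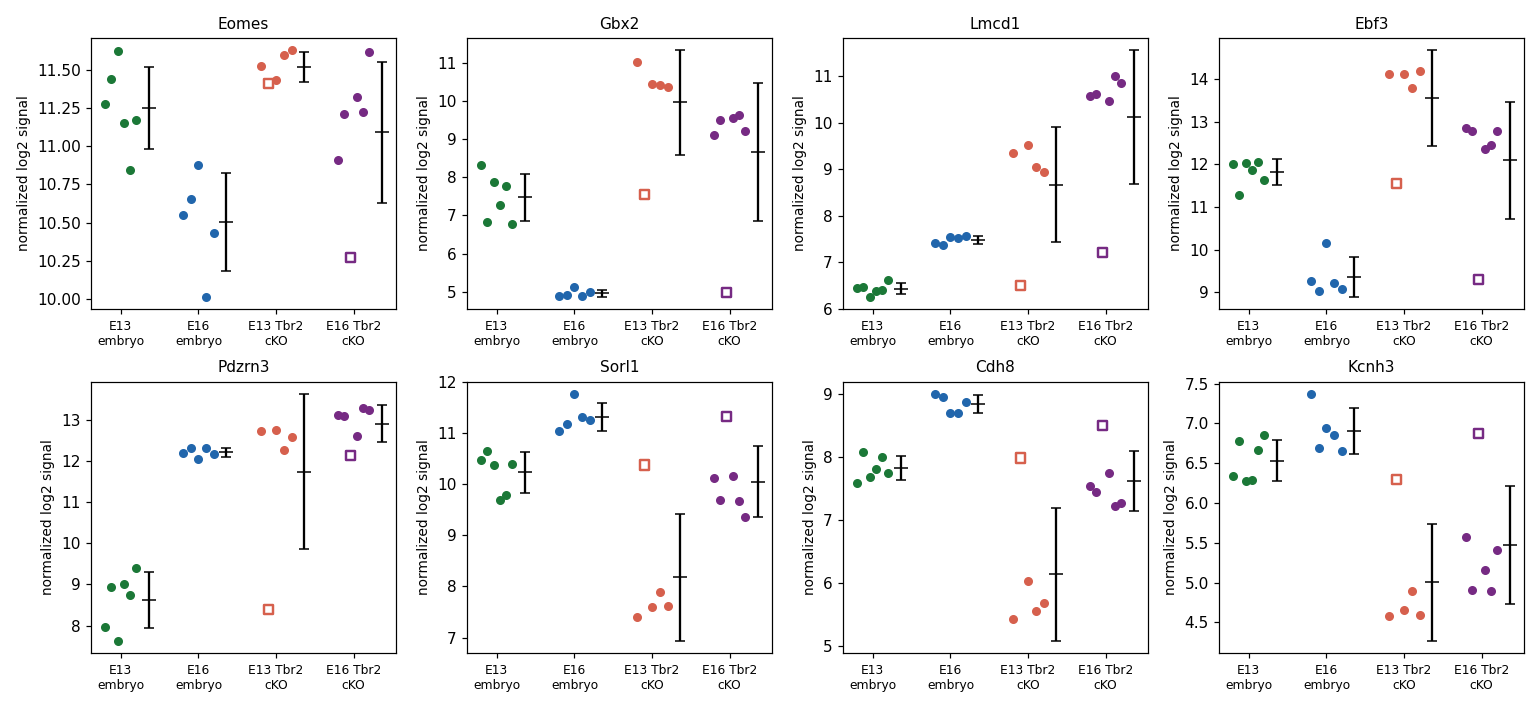
Normalised log2 signal of Eomes and 7 genes called between genotypes, with 1 point per array in the 4 embryonic groups and the mean ± SD of each group as a black bar. Open squares mark array 2 of the E13 cKO group and array 3 of the E16 cKO group. Eomes is not lower in the arrays labelled cKO, and for Gbx2 the other arrays labelled cKO lie between 10.38 and 11.04 at E13 and between 9.11 and 9.65 at E16.

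Whether the stage change depended on the genotype was tested with the interaction of both. The neuropeptide gene Nts had a stage change that was 1.41 ± 0.24 (SE) more positive in the arrays labelled cKO (limma adjusted p = 0.023). For Tac2 it was more negative, at -1.48 ± 0.26 (SE; adjusted p = 0.023). Among the 4 embryonic groups Nts was above background in E13 embryo alone and Tac2 in E16 embryo alone, so both sizes depend on the background level. Eomes had an interaction of 0.32 ± 0.28 (SE; adjusted p = 1.0). These 2 genes were the calls among 10663 genes, with 381 at an unadjusted p under 0.05, and no gene list passed camera (lowest adjusted p = 0.062, for 5 lists). In limma 0 genes passed with no normexp step, with median scaling, with no filter on dim probes or with only the compared groups in the fit. For Tac2 another probe, which the filter removes, stood for the gene with no filter. Its interaction was -0.58 and did not pass. Without each of the 22 embryonic arrays in turn, Nts lost its call 13 times and Tac2 12 times, and 5 times Tac2 did not pass the filter. Without the 2 arrays that lay among the embryo arrays 23 genes were more positive and 38 more negative, among them Pdzrn3, at -3.10 ± 0.32 (SE), and 3 lists passed camera upwards: intermediate progenitors, Cajal-Retzius cells and axon guidance (adjusted p = 0.010 each, and adjusted p = 0.40 each with an estimated correlation).

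Sorted P2 neurons were compared with E16 embryo to describe the Tbr2 lineage after birth. Eomes was 26.0-fold lower, at 5.81 ± 0.41 (SD, n = 5) against 10.51 ± 0.32 (SD, n = 5), a log2 change of -4.70 ± 0.21 SE (limma adjusted p = 1.0e-16), in 5 of 5 arrays. The proneural gene Neurog2 fell 36.1-fold, Fzd2, a Wnt receptor gene, at least 20.4-fold, and Phf21b 16.7-fold. Nrgn, a postsynaptic calmodulin-binding protein gene, rose at least 38.0-fold, from a level that no E16 embryo array held above background to 11.01 ± 0.19 (SD, n = 5). Among the largest rises were also Ttr, the main secreted product of the choroid plexus, at least 128-fold, the endothelial gene Cldn5, at least 35.1-fold, the vascular gene Igfbp7, at least 45.6-fold, and Laptm5, a gene of blood and immune cells, 64.6-fold. Eomes was above background in 4 of 5 P2 arrays, and Laptm5 in 1 of 5 E16 embryo arrays. Of 10663 genes 3237 rose and 4438 fell, with at least a 2-fold change for 1650 and 1561. With each array scaled to a common median, 3444 rose and 3346 fell, so the excess of falls was not kept. The median over all genes was -0.136 on the log2 scale and -0.0145 with each array scaled to a common median, so that changes of that size carry no direction.

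Intermediate progenitor genes were lower and synaptic genes higher in the P2 neurons. All 15 measured intermediate progenitor genes fell, 15 also when adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.073 with an estimated correlation), Rhbdl3 15.5-fold (above background in 3 of 5 P2 arrays) and Mfap4 11.5-fold among them. Cell cycle genes fell in 15 of 18 (1 risen and 15 fallen when adjusted over the list alone; camera adjusted p = 0.0049, and adjusted p = 0.41 with an estimated correlation), with Top2a (above background in 4 of 5 P2 arrays) 6.60-fold lower. Chromatin regulators fell in 15 of 19 and 1 rose (15 and 1 when adjusted over the list alone; camera adjusted p = 0.010, and adjusted p = 0.20 with an estimated correlation), with the remodeller gene Chd4 3.30-fold and the histone methyltransferase gene Ezh2 2.77-fold lower. Synaptic protein genes rose in 15 of 18 and 2 fell (15 and 2 when adjusted over the list alone; camera adjusted p = 9.2e-05, and adjusted p = 0.039 with an estimated correlation), including Sv2b, 22.5-fold, and Syt1, 6.78-fold. Glutamate receptor and channel genes rose in 9 of 17 and 3 fell (9 and 3 when adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.24 with an estimated correlation), with Grm5 28.0-fold (above background in 1 of 5 E16 arrays) and Scn2a 7.98-fold higher. Cajal-Retzius genes rose in 5 of 7 (5 when adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.24 with an estimated correlation), with Ndnf at least 7.60-fold and Reln 7.63-fold higher.

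Cortical layer genes were called in both directions in the P2 neurons. Deep-layer genes rose in 9 of 15 and 5 fell, with Ccn2 at least 17.8-fold and Nr4a2 8.99-fold higher (camera adjusted p = 0.057). Upper-layer genes rose in 6 of 11 and 3 fell, with Dkk3 13.6-fold and Mef2c 7.73-fold higher (camera adjusted p = 0.10). Delta protocadherins split 5 to 3 of 9, with Pcdh17 3.82-fold higher, and newborn neuron genes 6 to 5 of 15, with Gap43 4.19-fold higher and Rnd2 5.27-fold lower. Axon guidance genes split 5 to 9 of 20, with Unc5c 4.38-fold higher and Epha3 2.85-fold lower, and radial glia genes 5 to 6 of 16, with Tnc 6.69-fold higher and Lhx2 3.29-fold lower.

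Markers of other cell types were higher in the P2 neurons beside these neuronal genes. All 11 microglia genes rose, 11 also when adjusted over the list alone (camera adjusted p = 2.2e-09, and adjusted p = 0.038 with an estimated correlation), among them C1qc at least 16.6-fold and Cx3cr1 at least 14.5-fold. All 10 measured endothelial and pericyte genes rose, 10 when adjusted over the list alone (camera adjusted p = 2.8e-07, and adjusted p = 0.073 with an estimated correlation), Flt1 at least 13.4-fold among them. All 5 measured meninges genes rose, 5 when adjusted over the list alone (camera adjusted p = 0.0060, and adjusted p = 0.24 with an estimated correlation), led by Dcn, at least 17.9-fold. Astrocyte genes rose in 5 of 7 (6 when adjusted over the list alone; camera adjusted p = 0.0065, and adjusted p = 0.24 with an estimated correlation), Apoe 22.4-fold (above background in 3 of 5 E16 arrays) among them. Oligodendrocyte lineage genes rose in 3 of 4 (4 when adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.24 with an estimated correlation), Olig1 19.3-fold among them. Immediate early genes rose in 6 of 7 (6 risen and 1 fallen when adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.24 with an estimated correlation), Egr1 49.1-fold (above background in 4 of 5 E16 arrays) and Fos 22.6-fold. Their list also stands for dissociation stress and marks no cell type, and an effect of the sort was not tested. The filter on dim probes keeps a gene silent in all embryonic arrays only if all 5 P2 arrays hold it. With no filter 11 of 11 microglia, 12 of 13 endothelial, 8 of 10 meninges, 5 of 9 astrocyte, 5 of 7 oligodendrocyte lineage and 7 of 12 immediate early genes on the array rose.

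Interneuron genes varied widely between the P2 arrays. Of 9 genes of ventral progenitors and interneurons 5 rose (3 when adjusted over the list alone; camera adjusted p = 0.084), Npy 40.3-fold and Gad1 9.62-fold (above background in 3 and 2 of 5 E16 arrays), and the transcription factor gene Dlx1 stood at 8.32 ± 2.37 (SD, n = 5). Choroid plexus genes rose in 2 of 5, skeletal muscle genes split 1 to 1 of 4, and of 2 erythroid and 2 liver genes 0 and 1 rose. The P2 arrays differ from the embryo arrays in age, in the sort and in the deposited table at once, and the design cannot separate these.

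**Figure D4:**
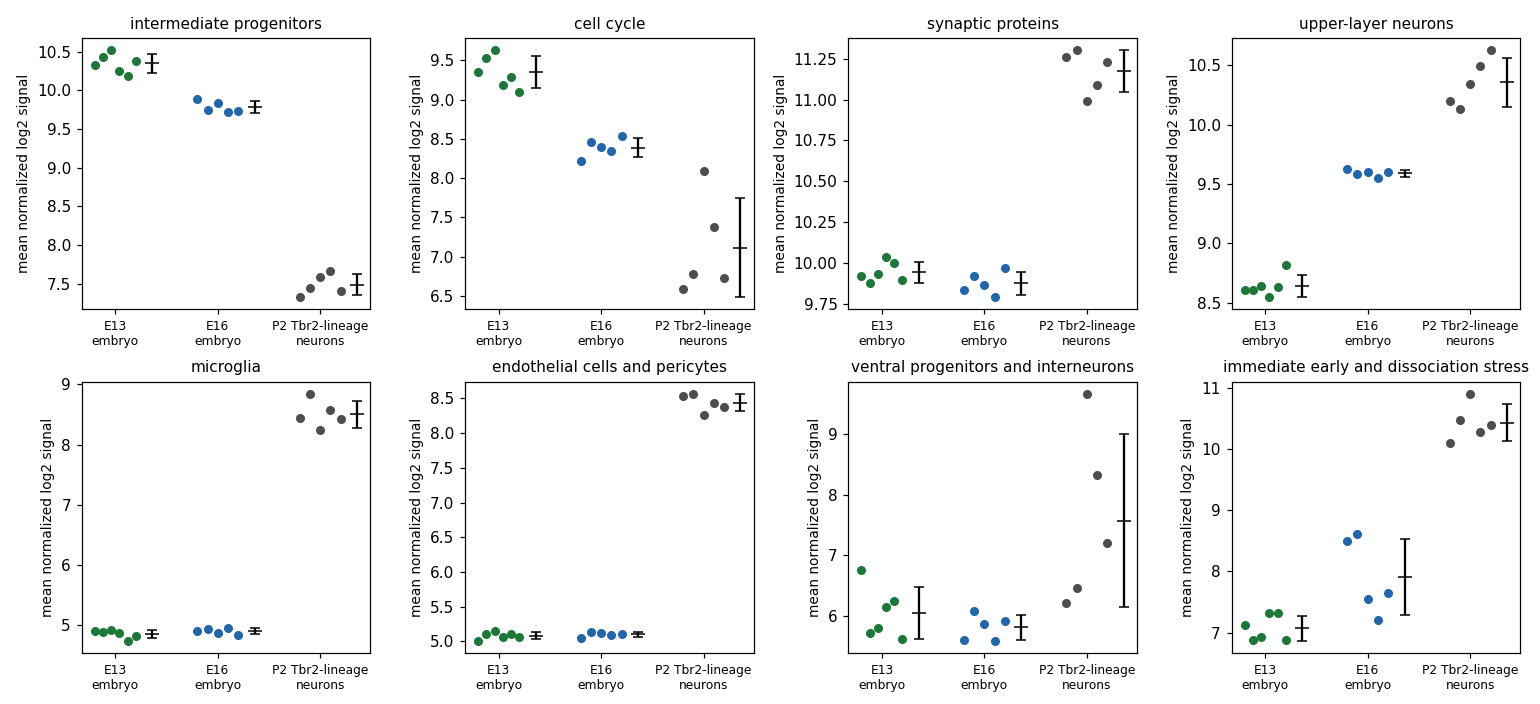
Mean normalised log2 signal over the measured members of 8 gene lists, with 1 point per array in E13 embryo, E16 embryo and the P2 neurons and the mean ± SD of each group as a black bar. Intermediate progenitor and cell cycle genes are lower and synaptic, microglia, endothelial and immediate early genes higher in the P2 neurons, while the upper-layer list did not pass against E16 embryo and interneuron genes are spread between the P2 arrays.

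The P2 neurons were also compared with E13 embryo. Eomes was 43.6-fold lower (log2 change -5.45 ± 0.20 SE; limma adjusted p = 1.5e-18), Neurog2 53.9-fold, Tfap2c 45.6-fold and Fezf1 at least 77.6-fold, while the calcium-binding protein gene Caln1 rose 111-fold, from 5.70 ± 0.16 (SD, n = 6) to 12.49 ± 0.13 (SD, n = 5). Caln1 was above background in 3 of 6 E13 arrays, and Eomes and Tfap2c in 4 of 5 P2 arrays each. All 15 intermediate progenitor genes fell (15 when adjusted over the list alone; camera adjusted p = 5.6e-07, and adjusted p = 0.035 with an estimated correlation), and 17 of 18 cell cycle genes fell (17; camera adjusted p = 1.8e-05, and adjusted p = 0.24 with an estimated correlation). Synaptic protein genes rose in 15 of 18 and 2 fell (15 and 2 when adjusted over the list alone; camera adjusted p = 8.9e-05, and adjusted p = 0.035 with an estimated correlation), with Camk2b 3.70 higher on the log2 scale. Upper-layer genes rose in 8 of 11 and 1 fell (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0031, and adjusted p = 0.068 with an estimated correlation), with Mef2c 25.1-fold higher and Inhba (above background in 1 of 6 E13 arrays) 4.39 higher on the log2 scale. Glutamate receptor and channel genes rose in 10 of 17 and 1 fell, and chromatin regulators fell in 13 of 19 and 2 rose (camera adjusted p = 0.0031 and 0.019, and adjusted p = 0.12 and 0.20 with an estimated correlation).

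Cajal-Retzius genes split between P2 and E13, with 3 risen and 4 fallen of 7, Ndnf at least 7.84-fold higher and Ebf2 (above background in 2 of 5 P2 arrays) 16.2-fold lower. Markers of other cell types were higher here too: 11 of 11 microglia genes, 10 of 10 endothelial genes, 5 of 5 meninges genes, 6 of 7 astrocyte genes and 4 of 4 oligodendrocyte lineage genes rose, beside 6 of 7 immediate early genes. With no filter 11 of 11, 11 of 13, 8 of 10, 6 of 9, 6 of 7 and 7 of 12 of those on the array rose in that order. Their camera adjusted p was 8.7e-09, 5.6e-07, 0.0053, 0.022, 0.036 and 0.0031, and the adjusted p was 0.035, 0.071, 0.22, 0.30, 0.22 and 0.20 with an estimated correlation. Of 10663 genes 3382 rose and 4502 fell, with at least a 2-fold change for 1767 and 1680, and with each array scaled to a common median 3442 rose and 3772 fell.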

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

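Of the tests below, those of the deposited tables, exchanged labels, another genotype, poor signal and other cells among the P2 neurons were chosen only after the result was seen, as were the 2 tissue lists, the check for genes left out of them, the test of a background in the P2 arrays as given here and the removal of the filter for the P2 markers.

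In the arrays labelled cKO, Gbx2, Lmcd1 and 6 other genes were higher than in embryo at both stages. A difference between the deposited tables of the embryo and cKO arrays would shift every array labelled cKO, yet at 2 of 2 stages an array labelled cKO lay within the range of the embryo arrays in the genes called at the other stage, which argues against it as the whole cause. Thalamus and habenula tissue stays open: a list of 8 measured markers differed by 0.060 over both stages (95% limits -0.16 to 0.28), by 0.193 at E13 (-0.120 to 0.505) and by -0.0718 at E16 (-0.385 to 0.241), and the upper limit met the bound of 0.5 fixed against it before its members were measured, but that bound was wrong, as the members moved both ways and the list left out Gbx2 and Pou4f1, genes of this region that rose. Olfactory bulb tissue stays open as well: 7 measured markers differed by -0.17 (-0.28 to -0.07) and met the same bound, but the list left out Cdhr1 and Th, which rose at E16 and E13. The genotype, which the labels name, may account for these genes and stays open too, as do parents and litter, which were not tested.

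Array 2 of the E13 cKO group and array 3 of the E16 cKO group lay at the levels of the embryo arrays. In the 52 genes called at E16 the first differed from embryo by 0.04 on average (other cKO arrays 0.74 to 0.89, embryo arrays -0.20 to 0.17), and in the 155 genes called at E13 the second differed by -0.03 (0.57 to 0.66, and -0.04 to 0.06). An exchange of labels between embryo and cKO arrays of a stage would put an embryo array at the level of the other cKO arrays, and the smaller gap between them was 0.51. Poor signal was argued against by the share of detected probes, 39.0% and 37.8%, which ranked 3 and 4 from the lowest in their groups. Tissue of another genotype on these 2 arrays, with a larger difference from embryo of 0.0442, is a candidate explanation and stays open, as does a difference in how completely the gene was deleted, which was not tested.

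Markers of other cell types were higher in the P2 neurons than in the embryo arrays. A background that differs between the tables adds to all probes of an array alike, and was argued against by the deposited signals: the median of endothelial and microglia markers less that of 41 genes of tissues absent from cortex (Hox, skeletal muscle and liver genes, no filter) of the same array was 421 higher in P2 (lower 95% limit 217; P2 arrays 197 to 646, embryo arrays -0.745 to 6.53). Cells of other types among the sorted P2 cells stay open: of the 24 endothelial and microglia markers on the array, with no filter, 21 were detected in every P2 array and higher than in E16 embryo, short of the 9 in 10 set for this test, and Kdr, Pdgfrb and Kcnj8 were not, while all 21 that passed the filter, as first tested, were, though genes silent in all embryonic arrays pass it only if all 5 P2 arrays hold them. A sort for GFP would remove cells without it, and C1qc and Cldn5 were at least 16.6-fold and 35.1-fold higher. Age stays open, as the embryo arrays are younger and their sort is not known.

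Other splits of the same arrays were counted against each number of called genes. Of 100 splits, 1 gave as many genes as the real one, the real one itself, for E16 against E13 in embryo (2541 genes, highest other 1660) and in cKO (2774, 1935), and for P2 against E16 (7675, 4614) and against E13 (7884, 7045). That argues against chance, though 100 splits cannot reach a share below 1 in 100. For P2 against E13 the highest other split came near the real count. Between genotypes at E13, 3 of 100 splits, the real one included, gave as many as the 155 genes, with 331 as the highest other. That met the limit set for this test beforehand. As 2 other splits called as many or more, and several comparisons were tested without correction, it argues only weakly against chance. At E16, 7 of 100 gave as many as the 52 genes (highest other 280), and for the interaction 8 of 100 gave as many as the 2 genes (highest other 33), so chance was not excluded for either. The splits that called several times the real count point to a structure of the samples: the highest at E13 put array 2 with 5 of 6 embryo arrays and 0 other cKO arrays, and the highest at E16 put array 3 with 5 of 5 embryo arrays and 0 other cKO arrays.

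Single arrays lay far from the rest of their group in 21 of 124 groups of a named gene. Chance gives about 1 in 20 for independent groups, but these groups share arrays. Many of the genes were also named because they differed between genotypes, where an array at embryo levels must stand apart. The count is therefore no measure of a general excess, and most of it came from 2 arrays. Array 2 of the E13 cKO group stood apart in 9 of them: Bcl6 at 7.30 (others 5.93 to 6.32), Dlk1 at 10.95 (12.46 to 12.80), Pdzrn3 at 8.39 (12.25 to 12.74), Gbx2 at 7.56 (10.38 to 11.04), Rgs4 at 7.69 (10.19 to 11.05), Slco4a1 at 5.15 (7.44 to 8.11), Lmcd1 at 6.51 (8.94 to 9.53), Sorl1 at 10.38 (7.41 to 7.89) and Cdh8 at 7.98 (5.42 to 6.03). Array 3 of the E16 cKO group stood apart in 8: Fezf1 at 7.78 (4.70 to 5.22), Gbx2 at 4.98 (9.11 to 9.65), Ebf3 at 9.30 (12.36 to 12.86), Lmcd1 at 7.21 (10.47 to 11.01), Tac2 at 5.59 (4.48 to 4.77), Kcnh3 at 6.87 (4.90 to 5.58), Hpca at 10.48 (8.38 to 9.12) and Trim9 at 10.60 (9.16 to 9.57). The others were Sla at 9.45 in array 5 of E16 cKO (10.30 to 10.71), Ebf3 at 10.16 in array 3 of E16 embryo (9.04 to 9.27), Cdhr1 at 5.12 in array 4 of E16 embryo (4.52 to 4.58) and Ttr at 7.45 in array 1 of E13 embryo (4.72 to 5.68).

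The stage change differed between genotypes by limma's interaction test for Nts, by 1.41 (E13 embryo arrays 5.67 to 6.62, E16 embryo 4.56 to 5.17, E13 cKO 5.02 to 5.44, E16 cKO 4.78 to 5.83), and for Tac2, by -1.48. Both sizes depend on the background level, as Nts was above background in E13 embryo alone and Tac2 in E16 embryo alone among the embryonic groups. Among 3239 kept probes with no gene symbol, which no comparison used, 29 passed between genotypes at E13 (10 higher, 19 lower) and 4 at E16 (1 higher, 3 lower).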

How the results depend on the processing

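The replicate block and the fit without array 2 of the E13 cKO group and array 3 of the E16 cKO group were tests chosen only after the result was seen. Leaving the single arrays aside, 2923 results of single genes kept direction and side of the threshold, 91 lost and 2 gained their call, and 1258 list results kept, 30 lost and 28 gained theirs. Of the counts of genes 188 stayed within 1.5 times and 88 moved. With single arrays left out, 3623, 182 and 2 single genes kept, lost and gained their call and 1 reversed, 1760, 16 and 51 lists did, and 222 counts stayed while 126 moved. Slide as a block was not run, because the columns give no slide. Below, list values are medians of log2 changes with camera adjusted p in parentheses. The cause of a change was not tested, except where another probe of a gene is named. Without normexp the skeletal muscle list between stages in cKO gave -0.33 (0.057), deep-layer genes between P2 and E16 0.84 (0.046), and the interaction 0 higher and 0 lower genes. With median scaling 651 genes were higher between stages in embryo, 582 in cKO and 52 between genotypes at E13, and the interaction gave 0 and 0. There muscle between stages in cKO gave -0.56 (0.052), intermediate progenitors at E13 0.19 (0.037), Cajal-Retzius genes at E16 0.26 (0.0097) and in the interaction 0.75 (0.035), and ventral genes at E16 0.27 (0.0097). With the series matrix values, which hold fewer genes, 47 were higher between genotypes at E13, 7 higher and 14 lower at E16, and 0 and 0 in the interaction. Cell cycle genes gave -0.45 (0.090) between stages in embryo, -0.46 (0.094) in cKO, -0.52 (0.60) for P2 against E16 and -0.97 (0.27) against E13. Immediate early genes gave 0.39 (0.090) between stages in embryo and 1.48 (0.098) for P2 against E16, intermediate progenitors -0.51 (0.17) between stages in cKO, radial glia 0.17 (0.42) and synaptic genes -0.031 (0.26) at E13, upper-layer genes -0.22 (0.012) at E16 and axon guidance 0.16 (0.0090) in the interaction. With no filter 13 genes were higher and 12 lower at E16, and 0 and 0 in the interaction. Muscle gave -0.084 (0.23) between stages in embryo and -0.14 (0.20) in cKO, immediate early genes 0.30 (0.090) between stages in embryo, newborn neuron genes 0.20 (0.044) between stages in cKO, intermediate progenitors 0.18 (0.0055) and meninges 0.29 (0.034) at E13, ventral genes -0.37 (0.025) and choroid plexus genes -0.39 (0.025) in the interaction, deep-layer genes 0.94 (0.028) for P2 against E16 and delta protocadherins 0.61 (0.042) against E13. With detection in every array of a group, intermediate progenitors at E13 gave 0.21 (0.040). With the mean of all probes, glutamate receptor genes between stages in embryo gave 0.25 (0.069), newborn neuron genes at E16 0.10 (0.013) and chromatin regulators for P2 against E13 -0.42 (0.088). With only the compared groups in the fit, 7 genes were higher and 4 lower at E13, 1 and 9 at E16, and 0 and 0 in the interaction. Fewer arrays alone do not account for this, as 1370 were higher and 1469 lower between stages in embryo, more than in the main fit. Between stages in cKO 1025 were higher and 1245 lower, fewer than in the main fit. The genotype calls of the main fit thus rest on a spread estimated over all groups. Choroid plexus genes between stages in embryo gave -0.73 (0.0499), intermediate progenitors 0.18 (0.012) and synaptic genes -0.047 (0.066) at E13, ventral genes 0.30 (0.0082) at E16 and deep-layer genes 0.94 (0.048) for P2 against E16. With the replicate block, which needed the series matrix values, 865 genes were lower between stages in embryo, 950 in cKO, 34 higher and 44 lower at E13, 0 and 9 at E16 and 0 and 0 in the interaction. There intermediate progenitors gave -0.50 (0.056) between stages in embryo and -0.50 (0.16) in cKO, cell cycle genes -0.43 (0.13), -0.47 (0.091), -0.52 (0.64) for P2 against E16 and -0.96 (0.32) against E13, glutamate receptor genes 0.41 (0.052) and immediate early genes 0.36 (0.13) between stages in embryo and 1.48 (0.10) for P2 against E16. Axon guidance gave 0.51 (0.044) between stages in cKO, -0.087 (0.066) at E16 and 0.19 (0.0022) in the interaction, radial glia 0.20 (0.36) and synaptic genes -0.034 (0.26) at E13, and upper-layer genes -0.22 (0.035) at E16. Without both arrays named above, 209 genes were higher and 185 lower at E13, 131 and 133 at E16, and 23 and 38 in the interaction. Axon guidance gave 0.30 (0.049, and 0.34 with an estimated correlation) between stages in cKO, synaptic genes -0.066 (0.093) at E13, Cajal-Retzius genes 0.23 (0.0047, and 0.32) at E16, and in the interaction intermediate progenitors gave 0.33, Cajal-Retzius genes 0.51 and axon guidance 0.16 (0.010 each, and 0.40 each). At E16 intermediate progenitors gave 0.32 (1.7e-06, and 0.027) and delta protocadherins -0.28 (0.0072, and 0.045). Both thus passed with an estimated correlation too, in a fit whose choice of arrays favours such calls. Leaving out single arrays gave 12 to 190 genes higher and 15 to 169 lower at E13, 8 to 115 and 7 to 120 at E16, and 0 to 16 and 0 to 25 in the interaction. At E13 the counts were 50 and 42 without embryo array 4, 45 lower without 5, 47 and 48 without 6, and without cKO array 1 to 5 in order 12 and 15, 190 and 169, 30 and 29, 24 and 20, 30 and 29. At E16 they were 14 and 17, 8 and 7, 18 and 20, and 17 and 15 without embryo array 1, 2, 4 and 5, and 11 and 14, 115 and 120, 14 and 17, 16 and 13, and 12 and 13 without cKO array 2, 3, 4, 5 and 6. In the interaction they were 16 and 25 without array 2 of E13 cKO and 4 and 11 without array 3 of E16 cKO. Without most other single embryonic arrays 1 or both of its calls were lost. Gpr149, E13 Tbr2 cKO vs E13 embryo, ranged from -1.92 to 0.032 and reversed to 0.032 without E13 embryo array 1. That value came from another probe of the gene, which had the higher mean without array 1, 2, 4 or 5 of E13 embryo. With the probe used elsewhere its changes there were -1.35, -1.60, -1.51 and -1.41 (adjusted p = 0.031, 0.033, 0.045 and 0.048), so neither the reversal nor the 3 calls lost there were changes of that probe. The other probe gave 0.032, -0.13, -0.11 and -0.14 there and never passed, so it did not show the fall of Gpr149. Of the results of named genes without single arrays, 5 rested on another probe. With no filter Tac2 did so too, and with the probe used elsewhere its change there was -1.52 (adjusted p = 1.8e-04) at E16 and -1.48 (adjusted p = 0.047) in the interaction. The other Tac2 probe, which the filter removes, gave -0.54 (adjusted p = 0.38) at E16 and -0.58 in the interaction and passed in neither. List medians ranged at E13 from 0.34 to 0.74 (choroid plexus), 0.039 to 0.39 (endothelial), 0.14 to 0.21 (intermediate progenitors), -0.038 to 0.37 (meninges), 0.021 to 0.22 (microglia), 0.0961 to 0.340 (radial glia), -0.11 to -0.045 (synaptic) and 0.17 to 1.06 (ventral). At E16 they ranged from -0.16 to -0.060 (axon guidance), 0.058 to 0.53 (Cajal-Retzius), -0.16 to -0.053 (deep-layer), -0.52 to -0.10 (immediate early), -0.025 to 0.16 (newborn neurons), 0.0981 to 0.206 (muscle) and 0.16 to 0.40 (ventral). In the interaction they ranged from 0.050 to 0.18 (axon guidance), 0.50 to 1.08 (Cajal-Retzius), -0.68 to -0.32 (choroid plexus), -0.29 to 0.011 (endothelial), 0.068 to 0.27 (intermediate progenitors), -0.27 to -0.045 (microglia) and 0.13 to 0.23 (newborn neurons). Axon guidance between stages in cKO ranged from 0.20 to 0.35 and immediate early genes in embryo from 0.56 to 0.87. For P2 the ranges were 0.88 to 1.15 (deep-layer), 0.66 to 0.74 (upper-layer) and 1.02 to 2.29 (ventral) against E16, and 0.53 to 0.67 (delta protocadherins) and 0.26 to 1.29 (ventral) against E13.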

Other observations

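The genes and lists below were tests chosen only after the result was seen. Without array 2 of the E13 cKO group and array 3 of the E16 cKO group, 71 genes were higher in the arrays labelled cKO at both stages and 53 lower. Among the higher ones were the transcription factor genes Ebf1, Ebf2, Ebf3 and Pou4f1, the progenitor gene Insm1, the cell cycle gene Ccnd1 and the neuropeptide gene Gal. Among the lower ones were the cadherin genes Cdh8 and Cdh10, the protocadherin genes Pcdh9, Pcdh19 and Pcdh20, the guidance genes Robo2, Sema3a and Epha7, and the glutamate transporter gene Slc17a7. At E13 Pdzrn3 rose by 3.95 ± 0.23 (SE) on the log2 scale (limma adjusted p = 2.5e-11) and Sorl1 fell by 2.59 ± 0.19 (SE), and at E16 Ebf3 rose by 3.29 ± 0.20 (SE; adjusted p = 6.8e-11) and Lmcd1 by 3.21 ± 0.17 (SE). The 2 arrays were left out because of their own values in such genes, so these counts are larger by that choice. The changes and p-values are favoured by it as well and are no independent test.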
